A study of Mus musculus with 6 samples.

How the data were processed

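Poly-A RNA of bone-marrow LSK cells was sequenced in 6 libraries, 3 from wild-type littermates and 3 from Mc5r-null mice, as paired-end stranded libraries. The authors deposited 1 table of 55487 genes with 2 kinds of values per library. Counts are whole-number counts per gene, as the deposited column names and values show, with no normalization. FPKM values were deposited beside them. In 11546 genes checked, 100% of the ratios of count to FPKM between libraries equalled the ratios of the count totals within a tolerance of 0.001, so the FPKM values carry no further scaling between libraries. The labels name CASAVA 1.8, HISAT2, StringTie and edgeR and the genome build GRCm38, without roles, so the program that counted, its annotation release and its use of strand are not known. Of the gene IDs, 55227 (99.5%) were found in GENCODE mouse release 21, and 99.4% of these had the same chromosome, start and end.

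The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, libraries were scaled by TMM, and genotype was tested with the robust quasi-likelihood F-test. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values scale a library's counts by its total of all gene counts. Fold changes are the fitted ones of edgeR. Gene lists were tested two-sided with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 31 lists with at least 5 tested genes, leaving out the sex-linked genes. Intervals for genes with few counts are exact 95% intervals. They cover counting error only, since PCR copies are not independent molecules.

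The lists, the tests, their alternatives and the rule for naming genes were fixed before the data were examined. The rule took the melanocortin genes, the 10 largest changes in each direction among called genes with an average of at least 1 log2 CPM, non-overlapping groups and an official symbol, up to 4 members of each list with the smallest p, and the sex-linked genes. Other genes named in the text, which in the report are Slamf1, Procr, Mecom, Fgd5, Hlf, Igha, Mpo, Nr4a1, Cdkn1a, Pax5, Rnmt, Slc4a1, Alas2, C1qa, Pf4, Vpreb1, Srebf2, Ccl3, Xbp1, Ldlrad4 and Fam210a, were chosen after their values were seen. The 33 fixed lists held markers of other cell types that an LSK gate would be meant to remove. Some genes stand in more than 1 fixed list, so the lists are not independent. Esam and Robo4 are in the lists of long-term HSC and of adhesion, homing and niche receptors. Vwf is in those of long-term HSC, of megakaryocyte and erythroid progenitors and of stroma and endothelium. The lists of plasma cell markers and sinusoidal endothelium were added after the data were seen.

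Alternatives were RLE and upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom without and with sample weights, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, other thresholds, camera with an estimated correlation and fry. Added after the data were seen were fits without immunoglobulin genes and without genes with a 2-fold spread within a genotype. Equal replicate numbers of the genotypes did not correlate (0.00255, -0.0408 and -0.0240 across genes), and no block was used in the reported fit. In counts simulated from the fitted means and dispersions, with changes in 200 genes, the fit called 57% of 100 genes changed 1.5-fold and 84% of 100 genes changed 2-fold, and 16 of 14867 unchanged genes. Values of 3 genes chosen by the rule are not reported here, and the plot of list members leaves out 1 of them, while counts and tests of the lists include them. No library was left out, and with 3 libraries per genotype no test for outliers was made.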

Results

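RNA was sequenced from LSK cells of mouse bone marrow, the lineage-negative population positive for Sca-1 and Kit that holds the haematopoietic stem cells and multipotent progenitors. There were 6 libraries, 3 from wild-type littermates and 3 from mice lacking Mc5r, the melanocortin 5 receptor, a Gs-coupled receptor for peptides such as alpha-MSH. The series describes the mice as irradiated, with no dose or time given in the sources used here, and no unirradiated library was analysed, so the only comparison is between the genotypes. Gene counts summed to 14953169, 14929154 and 14903723 in the wild-type libraries and to 14054536, 14076870 and 13983016 in the Mc5r-null libraries (replicates 1, 2 and 3). Nothing in the labels says which mouse or how many mice each library came from, so p-values and SDs measure the spread between these libraries, which may be technical.

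The targeted gene was measured first. Mc5r (ENSMUSG00000007480, GRCm38 chromosome 18, positions 68337596 to 68342446, plus strand) has 1 annotated transcript with 2 exons, at 68337596 to 68337725 and at 68338673 to 68342446, and its coding sequence lies in both. The wild-type libraries held 181, 157 and 198 Mc5r counts and the Mc5r-null libraries 0, 0 and 1. The mean was 11.97 ± 1.39 CPM in wild type and 0.0238 ± 0.0413 CPM in Mc5r-null (SD, n = 3 each). Relative to all counts, the Mc5r-null libraries together held 0.198% of the wild-type level (95% counting interval 0.00501% to 1.11%), a ratio of 504-fold (90.1 to 19940). The count of 1 fell in replicate 3, and without that library the level was 0. Which part of the gene is deleted is not given in the sources used here, and the counts cover the whole gene. The neighbouring Rnmt, an mRNA cap methyltransferase gene, had 69.8 ± 1.06 CPM in wild type and 64.2 ± 1.95 CPM in Mc5r-null (SD, n = 3 each; edgeR adjusted p = 0.120). Beyond it, Ldlrad4 rose 1.36-fold from 11.2 ± 0.739 to 14.8 ± 1.27 CPM (edgeR adjusted p = 0.00793). Fam210a, between them, rose 1.13-fold (edgeR adjusted p = 0.0364), a call lost with DESeq2, with the replicate block and without any 1 library but wild-type replicate 3. Mc2r, the next melanocortin receptor gene on the same chromosome, had no count in any library, and neither did Mc3r or Mc4r. Mc1r had at most 2 counts in a library. Pomc, which encodes the precursor of the melanocortin peptides, had 1.92 ± 0.0992 CPM in wild type and 2.71 ± 0.496 CPM in Mc5r-null (log2 fold change 0.53 ± 0.19 SE, edgeR adjusted p = 0.0651, and 0.0288 without Mc5r-null replicate 1). Of the melanocortin list, these 2 genes were tested, with 1 lower and 0 higher; adjusted over the list alone, Pomc passed too, with 1 higher and 1 lower.

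**Figure D1:**
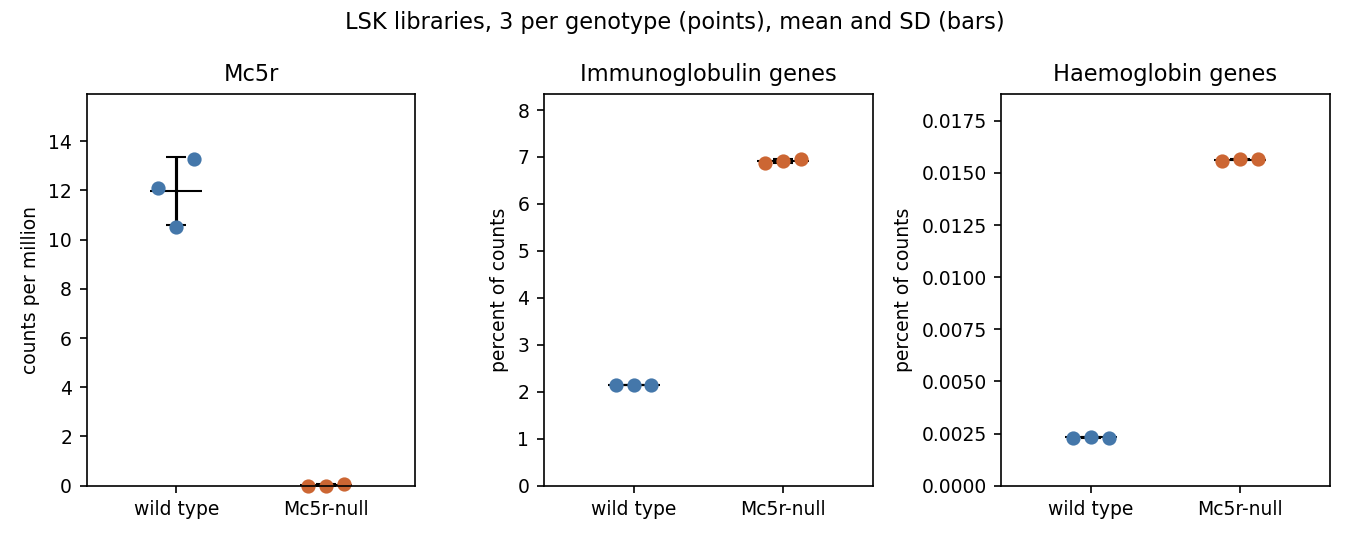
Mc5r in CPM and the shares of all counts, in percent, that fell on immunoglobulin and haemoglobin genes, for each of the 3 wild-type and 3 Mc5r-null libraries (points), with the mean and SD per genotype (bars). Immunoglobulin genes took 2.14% of counts in wild type and 6.91% in Mc5r-null, with no overlap between the genotypes.

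Genotype separated the libraries along the first principal component, which held 53.9% of the variance. Of 15257 genes tested, 2567 were higher and 2456 were lower in Mc5r-null LSK cells at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Most of these differences were small, with a median absolute log2 fold change of 0.36. A change of at least 2-fold was reached by 497 of the higher and 100 of the lower genes, and 182 of those 497 were immunoglobulin genes. With DESeq2 the counts were 1655 higher and 1446 lower. The values of the 3 wild-type and the 3 Mc5r-null libraries did not overlap for 4965 of the 5023 genes that passed, and for 49.8% of all genes tested, where 10% would be met by chance.

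Among genes with an average of at least 1 log2 CPM, the 10 largest increases were 7 immunoglobulin V segments, led by Igkv7-33 (17.2-fold) and Igkv9-129 (12.7-fold), and the alpha- and beta-globin genes Hba-a2 (12-fold), Hbb-bs (8.21-fold) and Hba-a1 (8.17-fold, 9.69 ± 0.967 to 77.4 ± 0.844 CPM, SD, n = 3 each). Reads of the V segments and of the paired globin genes can be shared between near-identical copies, so the split among them is uncertain. With the same limit, the largest decreases after Xist and Mc5r were in the inducible heat shock protein genes Hspa1b (5.38-fold, 148 ± 0.293 to 26.8 ± 0.446 CPM) and Hspa1a (4.41-fold), which are near-identical, and their neighbour Hspa1l (5.21-fold). Lrmda (4.41-fold) and the Polycomb gene Phc3 (3.38-fold) also fell. The genes of chains of the high-affinity IgE receptor fell, Ms4a2 (4.05-fold, 11.0 ± 0.937 to 2.63 ± 0.954 CPM) and Fcer1a (3.65-fold, 13.4 ± 0.387 to 3.58 ± 0.602 CPM), as did Ms4a4c, of the same gene family as Ms4a2 (3.35-fold). All of these had an adjusted p of at most 0.000245.

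**Figure D2:**
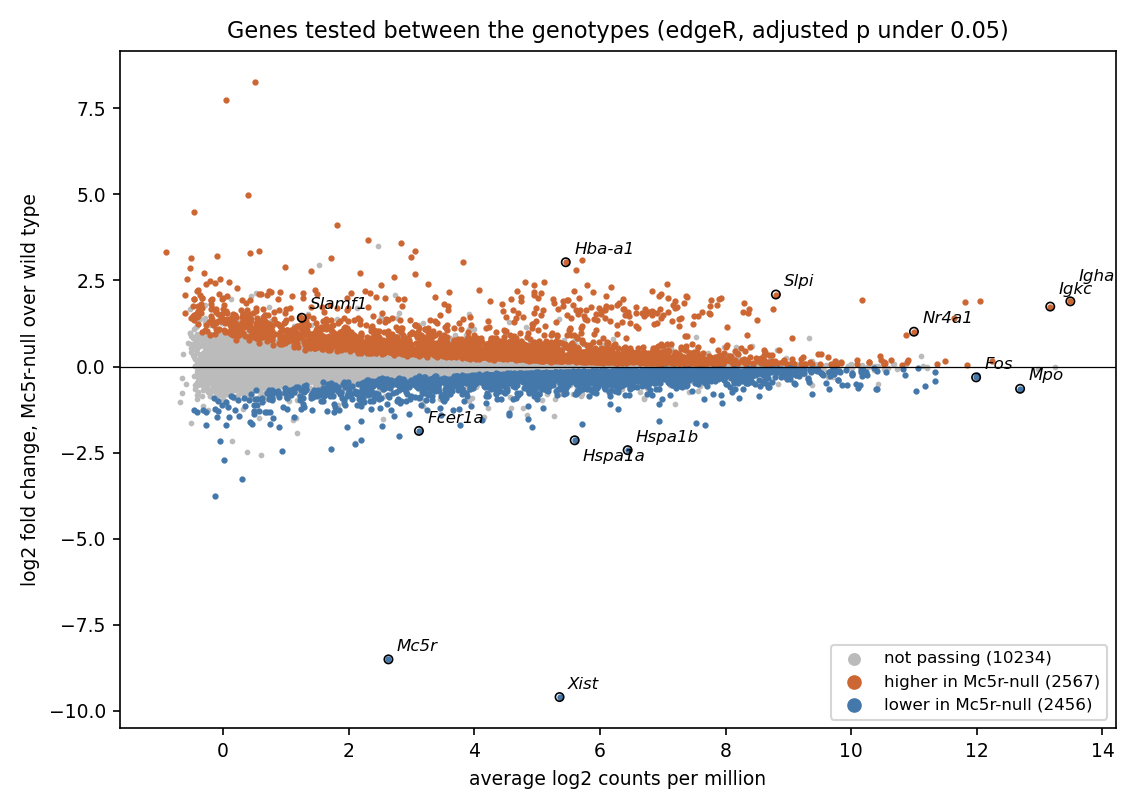
Log2 fold change of each of the 15257 tested genes, Mc5r-null over wild type, against its average log2 CPM over the 6 libraries. Orange points are the 2567 genes higher and blue points the 2456 genes lower in Mc5r-null at adjusted p under 0.05 (edgeR), grey points did not pass. Mc5r and Xist lie far below all other labelled genes.

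Genes typical of long-term haematopoietic stem cells were higher in Mc5r-null LSK cells. Of 28 such genes, 22 were higher and 1 was lower (23 and 1 adjusted over the list alone), with a median log2 fold change of 0.64. The endothelial protein C receptor gene Procr, a marker of repopulating stem cells, rose from 12.01 ± 0.932 to 20.8 ± 0.854 CPM, and Slamf1, which encodes the stem cell marker CD150, from 1.25 ± 0.332 to 3.28 ± 0.263 CPM (SD, n = 3 each). Fgd5 rose 2.08-fold, Mecom, which encodes a stem cell transcription factor, 1.62-fold, the transglutaminase gene Tgm2 2.18-fold and the interferon-induced membrane protein gene Ifitm1 1.48-fold. The member that fell was Egr1, an immediate early gene that marks quiescent stem cells, 1.19-fold lower, from 2021 ± 8.79 to 1657 ± 3.998 CPM. Hlf, another stem cell transcription factor, had 59.3 ± 17.3 CPM in wild type and 89.1 ± 3.97 CPM in Mc5r-null and did not pass (edgeR adjusted p = 0.1004). It passed with DESeq2 (adjusted p = 0.00316) and, with edgeR, without wild-type replicate 2 (log2 fold change 0.88, adjusted p = 2.3e-05). As a set the list was higher than other genes (camera, preset correlation, adjusted p = 5.97e-09), and the adjusted p was 0.0671 with an estimated correlation. Of 17 genes of multipotent and lymphoid-primed progenitors, 6 were higher and 2 lower (6 and 3 adjusted over the list alone, median 0.12, camera adjusted p = 0.192). The higher ones included the terminal transferase gene Dntt (1.79-fold, 385 ± 14.7 to 674 ± 22.0 CPM), Flt3, the cytokine receptor gene of multipotent progenitors (1.38-fold), Cd34 (1.21-fold) and Lsp1 (1.23-fold).

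Myeloid progenitor genes were lower. Of 16 genes, 14 fell and none rose (0 and 14 adjusted over the list alone), with a median log2 fold change of -0.65. The granule protease genes Prtn3 (1.58-fold, 1659 ± 10.1 to 1027 ± 16.5 CPM, SD, n = 3 each) and Ctsg (1.57-fold, 1679 ± 30.8 to 1041 ± 3.36 CPM) fell. The myeloperoxidase gene Mpo fell 1.56-fold from 8149 ± 592 to 5090 ± 136 CPM, the calreticulin gene Calr 1.48-fold, Plac8 1.74-fold and the macrophage colony-stimulating factor receptor gene Csf1r 1.76-fold. The camera adjusted p of the set was 3.30e-09, and 0.0629 with an estimated correlation. Genes of mast cells, basophils and eosinophils fell as well, 13 of 15 lower and 1 higher (13 and 1 adjusted over the list alone, median -1.03, camera adjusted p = 1.03e-07, adjusted p = 0.0629 with an estimated correlation). Basophil and mast cell protease genes Mcpt8 (3.17-fold), Prss34 (3.01-fold, 186 ± 1.88 to 60.2 ± 3.58 CPM) and Cpa3 (2.66-fold) and the eosinophil major basic protein gene Prg2 (1.73-fold) fell. The member that rose was the chemokine gene Ccl3. Of 18 mature neutrophil genes, 9 were lower and 4 higher (10 and 4 adjusted over the list alone, median -0.29, camera adjusted p = 0.0572). This list was called lower with limma-voom, with no filter on low counts and without wild-type replicate 1 (camera adjusted p = 0.0243, 0.0156 and 0.0476). The granule gene Camp fell 1.93-fold, the chitinase-like gene Chil3 1.72-fold, S100a8 1.41-fold and Lyz2 1.39-fold. Of 18 monocyte and macrophage genes, 11 were lower and 4 higher (11 and 6 adjusted over the list alone, median -0.41, camera adjusted p = 0.0724). It was called lower with limma-voom, with no filter on low counts and with the stricter filter (camera adjusted p = 0.0438, 0.0483 and 0.0264). Ms4a6c (2.14-fold), the chemokine receptor gene Cx3cr1 (2.07-fold) and the iron exporter gene Slc40a1 (1.63-fold) fell, while the complement gene C1qa rose from 0.223 ± 0.0387 to 1.04 ± 0.203 CPM.

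**Figure D3:**
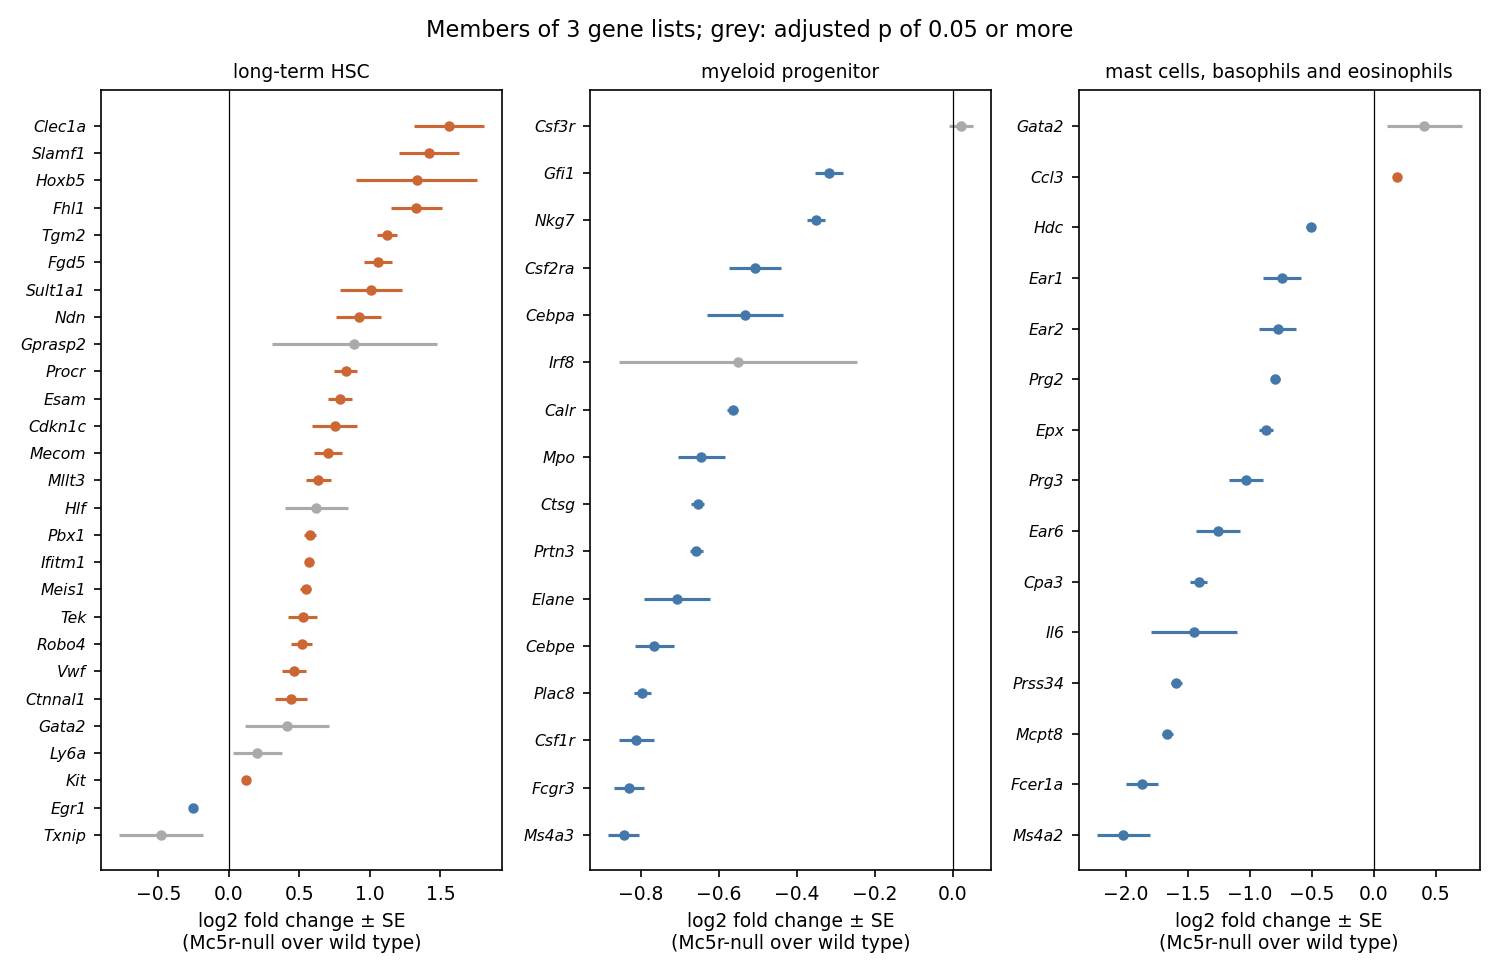
Log2 fold change, Mc5r-null over wild type, with its standard error (bars) for tested genes of the lists of long-term HSC (27 of the 28 genes), myeloid progenitor (16 genes), and mast cell, basophil and eosinophil genes (15 genes). Orange points were higher and blue points lower at adjusted p under 0.05 (edgeR), and grey points did not pass. The stem cell genes lie mostly right of 0 and the other 2 lists mostly left of it.

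Erythroid transcripts were scarce in both genotypes and higher in Mc5r-null. Of 13 erythroid genes, 12 rose and none fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 1.95. The beta-globin gene Hbb-bt rose 4.58-fold (9.24 ± 0.393 to 41.4 ± 0.787 CPM), the erythrocyte anion exchanger gene Slc4a1 4.59-fold and the haem synthesis gene Alas2 9.89-fold. Haemoglobin genes together held 0.00231 ± 0.0000363% of counts in wild type and 0.0156 ± 0.0000421% in Mc5r-null (SD, n = 3 each). The camera adjusted p was 2.57e-07, and 0.0671 with an estimated correlation. Among 18 genes of megakaryocyte and erythroid progenitors, 8 were higher and 2 lower (9 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.0324, adjusted p = 0.214 with an estimated correlation). The carbonic anhydrase genes Car1 (1.90-fold) and Car2 (1.58-fold), the water channel gene Aqp1 (1.54-fold) and Vwf, the von Willebrand factor gene (1.38-fold), rose, while the platelet factor gene Pf4 fell 2.08-fold. Without Mc5r-null replicate 3 this list was no longer called, with a camera adjusted p of 0.119.

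Immunoglobulin transcripts took 2.14 ± 0.00181% of all counts in wild type and 6.91 ± 0.0487% in Mc5r-null (SD, n = 3 each). Of 218 immunoglobulin genes tested, 203 were higher and 3 lower. The constant-region genes of IgA (Igha, 4946 ± 18.7 to 17950 ± 265 CPM, 3.72-fold), IgM (Ighm, 3.82-fold) and the kappa light chain (Igkc, 3.34-fold) rose. Of 16 B cell genes, 6 were higher and 5 lower (7 and 6 adjusted over the list alone). Their median was -0.15, while their mean was 0.15 and camera gave the direction higher with an adjusted p of 0.799, a direction that turned without Mc5r-null replicate 1. Beside Igkc and Ighm, the B cell receptor signalling gene Cd79a (1.97-fold) rose, while the surrogate light chain genes Igll1 (2.42-fold, 17.8 ± 0.522 to 7.19 ± 0.746 CPM) and Vpreb1 (2.16-fold) and the lineage factor gene Pax5 (2.003-fold) fell. Of 12 T and NK cell genes, 3 were higher and none lower (3 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 0.114), with the kinase gene Lck 1.47-fold higher and Cd3e, a chain of the T cell receptor complex, at 0.223 ± 0.194 CPM in wild type and 1.02 ± 0.168 CPM in Mc5r-null (SD, n = 3 each). Without Mc5r-null replicate 3 the edgeR adjusted p of Cd3e was 0.0621. The call of the perforin gene Prf1 was lost with DESeq2, with the replicate block and without wild-type replicate 1 or 3 or Mc5r-null replicate 1 or 3 (edgeR adjusted p between 0.0913 and 0.105 without each of these libraries). Of 13 dendritic cell genes, 2 were higher and 5 lower (2 and 5 adjusted over the list alone, median -0.06, camera adjusted p = 0.632). Siglech, a marker of plasmacytoid dendritic cells, fell 2-fold and Cd74, the invariant chain gene, rose 1.85-fold from 119 ± 15.6 to 214 ± 13.6 CPM. Stromal and endothelial genes were 6 higher and 0 lower of 11 (6 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.0324, adjusted p = 0.214 with an estimated correlation). Sparc rose from 1.85 ± 0.257 to 5.89 ± 0.633 CPM and Kdr, the VEGF receptor gene, from 0.580 ± 0.192 to 2.57 ± 0.197 CPM. This list was not called without wild-type replicate 2 (camera adjusted p = 0.0519) or with the replicate block (camera adjusted p = 0.0721).

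Replication genes were modestly lower in Mc5r-null. Of 26 S phase genes, 15 fell and none rose (0 higher and 16 lower adjusted over the list alone, median -0.16). The ribonucleotide reductase gene Rrm2 fell 1.43-fold from 225 ± 1.35 to 154 ± 2.02 CPM, the cyclin gene Ccne2 1.82-fold, the origin licensing gene Cdc6 1.43-fold and the helicase gene Mcm4 1.13-fold. The camera adjusted p was 1.56e-05, and 0.0671 with an estimated correlation. Of 28 genes of G2 and mitosis, 10 were lower and 1 higher (10 and 1 adjusted over the list alone, median -0.07, camera adjusted p = 0.0218, adjusted p = 0.112 with an estimated correlation). Cenpe (1.25-fold), Anln (1.27-fold), Aurka (1.18-fold) and Ccnb2 (1.16-fold) fell. Without Mc5r-null replicate 3 the camera adjusted p of this list was 0.0530.

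The lists chosen for the response to irradiation held genes that rose and genes that fell. Of 27 p53 target genes, 7 were higher and 5 lower (9 and 6 adjusted over the list alone). Trp53inp1, which encodes a p53-induced nuclear protein, rose 1.94-fold from 53.1 ± 1.73 to 101 ± 0.556 CPM, while the antiproliferative gene Btg2 (1.35-fold), the kinase gene Plk2 (1.35-fold) and the pro-apoptotic gene Bbc3 (1.44-fold) fell. The cell cycle inhibitor gene Cdkn1a had 182 ± 8.96 CPM in wild type and 125 ± 70.5 CPM in Mc5r-null and did not pass (edgeR adjusted p = 0.441). Its Mc5r-null counts were 1220, 1142 and 2879, and without replicate 3 it was called lower (log2 fold change -1.08, edgeR adjusted p = 5.69e-06). Cdkn1a is thus among the genes with a 2-fold spread within a genotype that are described in the last paragraph. The cause of that spread was not tested, so the call without replicate 3 does not show a decrease. The list's median was -0.01, with a mean of 0.03 and the camera direction higher (adjusted p = 0.632). Among 30 DNA repair genes, 3 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.837), again with a median of -0.01, a mean of 0.03 and the camera direction higher, which turned without wild-type replicate 1 or Mc5r-null replicate 3. Xrcc5 (1.34-fold), Brca2 (1.34-fold) and Xrcc4 (1.30-fold) rose and the damage-marking histone gene H2ax fell 1.12-fold. The call of Xrcc4 was lost with DESeq2 and without wild-type replicate 1, Mc5r-null replicate 2 or Mc5r-null replicate 3 (edgeR adjusted p = 0.0570, 0.0558 and 0.0570). Of 19 apoptosis regulators, 5 were higher and 4 lower (5 and 4 adjusted over the list alone, median -0.05, mean 0.03, camera direction lower with adjusted p = 0.837). The pro-apoptotic gene Bcl2l11 (1.63-fold) and the inhibitor genes Birc3 (1.30-fold) and Birc2 (1.20-fold) rose and the pro-apoptotic gene Bak1 fell 1.19-fold. Of 12 genes of senescence and secreted inflammatory factors, 2 were higher and 3 lower (2 and 3 adjusted over the list alone, median -0.08, camera adjusted p = 0.408). Tgfb1 fell 1.18-fold, the chemokine gene Ccl2 2.20-fold and Il6 2.73-fold, and the gelatinase gene Mmp9 rose 1.24-fold.

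Of 21 heat shock and unfolded protein response genes, 13 fell and 4 rose (13 and 5 adjusted over the list alone, median -0.24, camera adjusted p = 0.00202, adjusted p = 0.0671 with an estimated correlation). Beside Hspa1a and Hspa1b, Sdf2l1 (1.47-fold) and Dnajb9 (1.53-fold), both of the endoplasmic reticulum, fell, while Xbp1, the transcription factor gene of the unfolded protein response and of plasma cells, was among those that rose. Of 18 immediate early genes, 11 fell and 5 rose (11 and 5 adjusted over the list alone, median -0.25, camera adjusted p = 0.00697, adjusted p = 0.0924 with an estimated correlation). Klf6 fell 1.55-fold from 1354 ± 0.300 to 856 ± 6.90 CPM, Klf4 1.52-fold, Klf2 1.43-fold and Fos 1.24-fold, whereas Nr4a1, an orphan nuclear receptor gene, rose 2.02-fold from 1370 ± 166 to 2700 ± 297 CPM. The wild-type counts of Klf6 (20255, 20215 and 20180) lay closer together than counting noise gives on average. Those of Hspa1b (2207, 2199 and 2204) did so too. Such small SDs among genes chosen by p or fold do not measure a spread between animals. Of 30 interferon response genes, 11 fell and 2 rose (11 and 2 adjusted over the list alone, median -0.20, camera adjusted p = 0.00303, adjusted p = 0.0671 with an estimated correlation). Usp18 (1.94-fold), Oas1a (1.40-fold) and Gbp3 (1.31-fold) fell, and the RNA sensor gene Ddx58 rose 1.23-fold. Of 23 NF-kB and inflammatory genes, 10 were higher and 2 lower (10 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.0690). This list was called higher with limma-voom, with no filter on low counts, without Mc5r-null replicate 3 and without immunoglobulin genes (camera adjusted p = 0.0448, 0.0483, 0.0446 and 0.0459). The inhibitor gene Nfkbia (1.28-fold, 634 ± 7.41 to 790.03 ± 6.397 CPM) and Traf1 (1.89-fold) rose, and the receptor gene Tlr2 fell 1.93-fold. Of 15 cAMP and CREB target genes, which lie downstream of a Gs-coupled receptor, 6 were higher and 4 lower (8 and 5 adjusted over the list alone, median 0.23, camera adjusted p = 0.455). The phosphodiesterase gene Pde4b rose 1.32-fold and the kinase gene Sik1 1.18-fold, and the phosphatase gene Dusp1 fell 1.58-fold. Of 21 genes of the PI3K, AKT, mTOR and FOXO pathway, 6 were higher and 2 lower (6 and 2 adjusted over the list alone, median 0.07, camera adjusted p = 0.320). Foxo3 (1.52-fold) and Foxo1 (1.67-fold) rose and the kinase gene Sgk1 fell 1.51-fold. Of 20 adhesion, homing and niche receptor genes, 7 were higher and 6 lower (7 and 8 adjusted over the list alone, median 0.01, camera adjusted p = 0.511), with the adhesion gene Esam 1.72-fold and the guidance receptor gene Robo4 1.43-fold higher and the chemokine receptor gene Cxcr4 1.25-fold lower.

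Of 26 oxidative phosphorylation genes, 17 fell and none rose (0 higher and 18 lower adjusted over the list alone, median -0.18, camera adjusted p = 1.26e-05, adjusted p = 0.0629 with an estimated correlation). The respiratory chain and ATP synthase genes Ndufb8 and Atp5o fell 1.39-fold and 1.40-fold, Uqcrc1 1.26-fold and Atp5a1 1.13-fold, from 912 ± 24.5 to 791 ± 4.12 CPM. Of 20 genes of cholesterol synthesis, 9 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.18, camera adjusted p = 0.00110, adjusted p = 0.0671 with an estimated correlation). The farnesyl diphosphate synthase gene Fdps fell 1.67-fold and Insig1 1.23-fold, and the member that rose was Srebf2, which encodes the pathway's transcription factor and whose call was lost with no filter on low counts and without wild-type replicate 2 or 3 or Mc5r-null replicate 2. Of 20 glycolysis genes, 9 were lower and 3 higher (9 and 4 adjusted over the list alone, median -0.06, camera adjusted p = 0.133, and 0.0483 with no filter on low counts). Pgam1 (1.34-fold), Eno1 (1.22-fold) and Ldha (1.16-fold) fell and Pfkl rose 1.19-fold. Of 19 antioxidant and NRF2 genes, 6 were lower and 3 higher (6 and 3 adjusted over the list alone, median -0.04, camera adjusted p = 0.455), with the glutathione reductase gene Gsr 1.48-fold and the NRF2 gene Nfe2l2 1.32-fold lower. Of 26 ribosomal protein genes, 6 were higher and 7 lower (6 and 8 adjusted over the list alone), with a median of 0.01, a mean of -0.01 and the camera direction lower (adjusted p = 0.799). Rps18 fell 1.24-fold and Rpl5 1.20-fold. Of 23 MYC target and ribosome biogenesis genes, 3 were higher and 7 lower (3 and 7 adjusted over the list alone, median -0.07, camera adjusted p = 0.257). Srm, the spermidine synthase gene, fell 1.24-fold and Ccnd2 rose 1.19-fold.

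**Figure D4:**
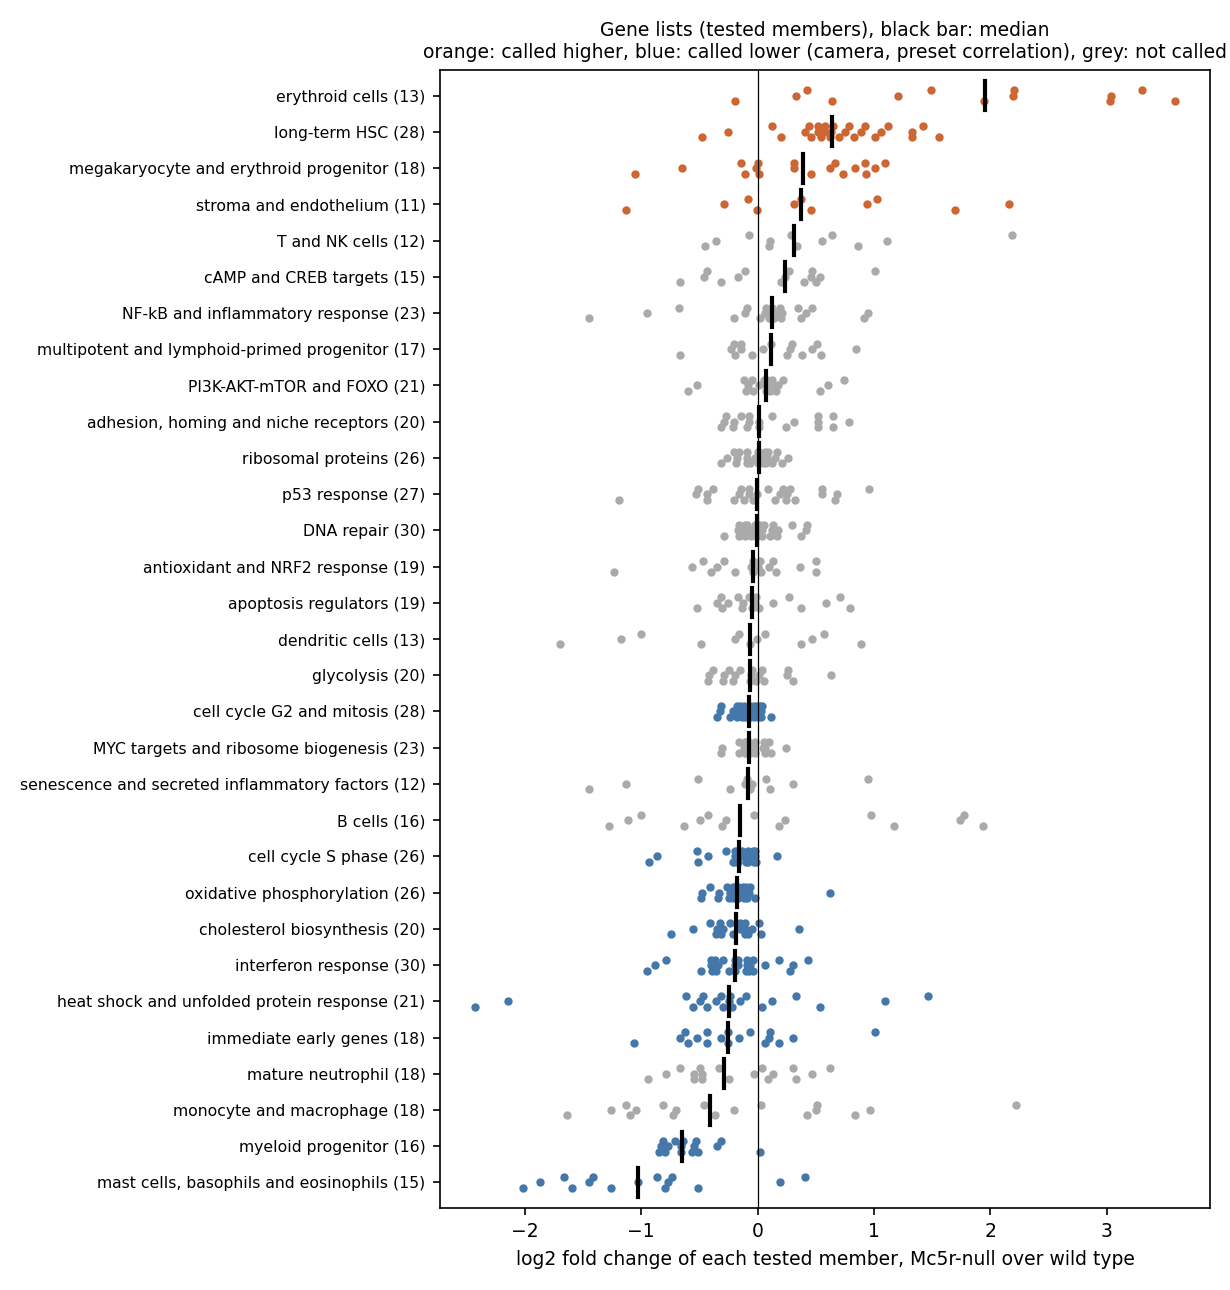
Log2 fold change, Mc5r-null over wild type, of each tested member (points) of the 31 gene lists tested, with the list's median (black bar). Orange lists were called higher (4) and blue lists lower (9) by camera with a preset correlation, and grey lists were not called. With an estimated correlation 0 of the 31 lists had an adjusted p under 0.05.

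In all, camera with a preset correlation called 13 of the 31 lists, 4 higher and 9 lower. With an estimated correlation, camera called 0 lists at an adjusted p under 0.05 and gave 11 an unadjusted p under 0.05, and fry, which tests a set's own direction, called 24.

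Xist, the X inactivation transcript, differed between the genotypes, with 1224, 1167 and 1281 counts in the wild-type libraries and 0, 2 and 2 in the Mc5r-null libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 2164, 2543 and 2078 counts in the wild-type and 2486, 2498 and 2450 in the Mc5r-null libraries, and Tsix had at most 0.335 ± 0.0675 CPM (SD, n = 3) in either genotype. This difference in Xist ran with genotype across every comparison above. Within a genotype, log2 CPM correlated across genes with Pearson's r between 0.990 and 0.991, and between genotypes with r between 0.976 and 0.977, where genes are not independent replicates. Counts of libraries of 1 genotype differed by more than sampling noise, with a mean chi-square of 6.12 to 8.37 per gene against 45.4 to 47.3 between genotypes. A few genes with large counts can dominate such a mean. Among genes with a mean of at least 20 counts, the median index of dispersion (chi-square per degree of freedom) was 1.09 within wild type. Within Mc5r-null it was 1.085, where counting noise alone gives 0.693. The excess over sampling noise may be technical and does not show that the libraries came from separate mice.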

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

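The settings without immunoglobulin genes and without genes with a 2-fold spread within a genotype were chosen after seeing the data, the others before. Of the 5023 genes called, 4963 were also called with RLE scaling, 4920 with limma-voom, 3009 with DESeq2 and between 3844 and 3925 without any 1 library, and none was called in the other direction under any of the refitted settings. With DESeq2, 1655 genes were higher and 1446 lower, and the cause was not tested. With a 2-fold threshold, 497 were higher and 100 lower, a stricter rule by construction. Without any 1 library, 2080 to 2124 genes were higher and 1986 to 2094 lower, with fewer libraries by construction. Camera called between 12 and 17 lists under the other scalings, filters, fits and left-out libraries, 0 with an estimated correlation and 24 with fry, which does not compare a list with other genes. The block by replicate number gave 2254 genes higher, 2148 lower and 12 lists, without stroma and endothelium. The Mc5r level ranged from 0% to 0.299% of wild type when 1 library was left out, and was 0% without Mc5r-null replicate 3, which held the single count. Over the named genes, 3272 comparisons with an alternative kept direction and side of the threshold, 95 lost the call, 8 gained it and 5 reversed. None of the genes that reversed was called in the reported fit, and Abl1 was called with the block (edgeR adjusted p = 0.00446). Without any 1 library the log2 fold change of Ccnd3 ranged from -0.97 to 0.28 (the latter without wild-type replicate 2), that of Abl1 from -0.15 to 0.62 (below 0 without wild-type replicate 3 and, at -0.030, without Mc5r-null replicate 2), that of Gpx1 from -0.94 to 0.0010 and that of Eif2s3y from -0.12 to 0.0021 (both above 0 without Mc5r-null replicate 3). Over the lists, 479 comparisons kept direction and side, 25 gained a call, 17 lost it (13 of these with an estimated correlation) and 6 reversed, none of them in a called list. The direction of the test turned for DNA repair without wild-type replicate 1 (median -0.0229) and without Mc5r-null replicate 3 (median -0.00664), where the medians without any 1 library ranged from -0.0229 to 0.013. It turned for B cells without Mc5r-null replicate 1 (median -0.266, range without any 1 library -0.266 to -0.0422) and without immunoglobulin genes (median -0.30). Under fry it turned to higher for apoptosis regulators (median -0.0502) and dendritic cells (median -0.0643). The cause was not tested, except that the B cell list holds immunoglobulin genes. The pseudocount alternative was not run, since counts were used. In counts simulated with 200 changed genes, 84% of 2-fold changes and 57% of 1.5-fold changes were called. In the data 5023 genes were called, so these shares need not hold for the reported fit.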

Other observations

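All tests of explanations in this part were chosen after the results were seen. Genes of plasma cells, the antibody-secreting cells, were higher in Mc5r-null. Of 12 markers outside the immunoglobulin genes, a list chosen after the data were seen that shares Xbp1 with the list of heat shock and unfolded protein response, 12 were higher, with a median log2 fold change of 1.22. Sdc1, which encodes CD138, rose from 33.1 ± 2.53 to 70.2 ± 4.36 CPM (SD, n = 3 each). The transcription factor gene Irf4 rose from 18.1 ± 1.20 to 41.9 ± 1.25 CPM and Tnfrsf17, which encodes the receptor BCMA, 2.93-fold. Of 199 immunoglobulin V segments tested, 187 were higher and 3 lower (median 1.58), the lower ones being Ighv7-4, Igkv8-26 and Igkv1-133, and all 12 constant-region genes tested were higher (median 1.84). Of 12 genes of sinusoidal endothelium, also chosen after the data were seen and 4 of them members of the list of stroma and endothelium, 10 were higher and none lower (median 1.15). Stab2 rose from 0.648 ± 0.318 to 2.87 ± 0.940 CPM and Ptprb from 0.246 ± 0.0387 to 1.33 ± 0.275 CPM. Among genes with an average of at least 1 log2 CPM outside immunoglobulin and haemoglobin genes, the 10 largest rises included the protease inhibitor gene Slpi (171 ± 4.52 to 713 ± 4.65 CPM), the epithelial adhesion gene Epcam (3.95-fold), the receptor gene Gpr55 (3.90-fold) and Reln (3.86-fold). Rac1, which encodes a small GTPase, fell from 316 ± 2.38 to 94.99 ± 6.37 CPM.

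Xist and Y-linked transcripts stood together in the wild-type libraries. At least 100 counts of both were present in 3 of 3 wild-type libraries. The 4 X-linked genes Kdm5c, Kdm6a, Ddx3x and Eif2s3x, which escape inactivation, had a median log2 fold change of -0.126 (bootstrap interval -0.242 to -0.101). That interval runs from the lowest to the highest of the 4 values, all below 0, so it could not include 0. The direction is the one that XX cells beside XY cells in the wild-type libraries would give. With DESeq2, however, none of the 4 was called. The calls of Kdm5c, Kdm6a and Eif2s3x were each lost without 1 or more single libraries. XX cells in the wild-type libraries would also leave Y-linked genes higher in Mc5r-null. Kdm5d was higher (log2 fold change 0.23, edgeR adjusted p = 0.0374), a call lost with DESeq2. Ddx3y (0.52, edgeR adjusted p = 0.0794), Uty (0.15, 0.299) and Eif2s3y (-0.037, 0.714) did not pass. The median index of dispersion of V segments within a genotype was 1.10, where counting noise alone gives 0.693. Their median CV was 5.09% within wild type and 4.04% within Mc5r-null. Differences of several fold, which would have spoken against 1 pool of RNA per genotype, were thus not typical. The V-segment index was 0.953 within wild type and 1.27 within Mc5r-null, against 1.09 and 1.085 for all genes. Immunoglobulin genes took 2.146%, 2.144% and 2.142% of counts in wild-type replicates 1, 2 and 3. This agreement argues against separate mice only as far as mice differ in V segments, which was not measured. Whether libraries of a genotype were drawn from 1 pool stays open, since no library is known to come from a single animal. The p-values above may therefore rest on technical replicates. The difference in Xist followed genotype in all 6 libraries, so the fits above do not separate sex-linked differences from genotype.

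The immunoglobulin rise was weighed next. Reads shared between V segments would leave the constant-region genes unchanged, and the smallest log2 fold change among these was 0.906. More RNA from plasma cells, which a lineage-negative gate would be meant to remove, may account for the rise: the median of the 12 markers was 1.22 (bootstrap interval 1.01 to 1.39), in a list chosen after the immunoglobulin rise was seen. The markers ranged from 0.333 to 1.55, below the median of 1.84 of the constant-region genes, which ranged from 0.906 to 1.96. Whether plasma cell RNA accounts for the whole rise was not tested. Whether more such cells passed the gate or lay in the marrow was not tested, and genotype itself stays open as the biological explanation.

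The long-term HSC list was higher and the myeloid progenitor list lower. Without immunoglobulin genes the medians were 0.647 and -0.643 and both lists were again called with the preset correlation, which argues against immunoglobulin counts moving the scaling, although with an estimated correlation neither list was called (adjusted p = 0.0671 and 0.0629 with all genes). RNA from endothelial cells, which the gate would be meant to remove, was weighed with 9 stem cell genes taken as not known from endothelium. They had a median of 0.646 (bootstrap interval 0.440 to 1.33), with 7 of 9 higher. These genes were chosen after the values were seen, from a list with 22 of 28 genes higher. Their rise argues against endothelial RNA as the whole rise only as far as that choice holds, and cannot exclude it. A lower share of myeloid cells alone would raise other transcripts alike. The stem cell list lay 0.521 above the multipotent and lymphoid-primed list (difference of medians, two-sided permutation p = 6e-04). The 10000 permutations were over genes, which are not independent. Log2 fold changes ranged from -0.48 to 1.56 in the former list and from -0.669 to 0.841 in the latter. The gap argues against an equal rise of both lists, but does not exclude a lower share of myeloid cells beside other changes. A larger share of stem cells in the gate, a change within cells and the difference in sex-linked transcripts stay open as well, and none of these was tested.

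With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 5023 genes and 13 lists, the highest of the others 3 genes and 5 lists, with 1 of 10 splits reaching the real value in each case. Each of the others put both genotypes in both groups. The difference between the genotypes then widened the spread within groups, so few gene calls could be foreseen there. Within 5 Mb of Mc5r, with Mc5r left out, 12 of 41 genes tested were called (29.3%), against 32.9% of all genes. With a change over 1.5-fold, 2 were called (4.88%), against 9.23% of all genes. A region of 5 Mb on chromosome 1 around the interferon-inducible Ifi200 and the Slam genes was chosen after its values were seen. There, 38 of 77 genes were called (49.4%), against 32.9% of all genes. With a change over 1.5-fold, 20 were called (26%, 7 higher and 13 lower), against 9.23% of all genes. Slamf1 and Fcer1a, named above as genes of cell types, lie in this region. Whether their changes belong to the region rather than to those cell types was not tested. Of 11 genes of the Ifi200 family there, 8 were lower, among them Ifi209 (2.86-fold), and 1 was higher, Ifi203 (log2 fold change 0.17, edgeR adjusted p = 0.0287), whose call was lost with DESeq2 and without wild-type replicate 2 or Mc5r-null replicate 1 or 3 (edgeR adjusted p = 0.0733, 0.0589 and 0.0878). Of 8910 genes with a mean of at least 200 counts in both genotypes, 125 had a 2-fold spread within wild type and 150 within Mc5r-null, and 61 had it in both, where chance would give 2.10. Examples were Gpx1, with 16505, 2604 and 15182 counts in the wild-type libraries, and Abl1, with 2367, 2330 and 702.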
